A study of Mus musculus with 5 samples.

How the data were processed

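The samples were 5 arrays of RNA from sorted mouse HSCs, 3 from cells cultured with DMSO and 2 from cells cultured with 5 µM ATRA, each for 24 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, stem and progenitor cells of C57BL/6 mice were cultured, HSCs were sorted by flow cytometry afterwards, RNA was isolated with a kit for small samples and treated with DNase, and biotin-labelled cRNA was made by in vitro transcription. Amplification of small amounts of RNA and the sort after treatment can both shape the values, the first through transcript loss and the second through which cells still meet the gate.

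The authors deposited log2 expression values, 1 value per array feature and array. The submitters' processing notes name RMA (robust multi-array average, without a version), oligo 1.36.1 and limma 3.28.20, with no role or order. The genome build and the array annotation they used are not given in the sources used here, and scanner files were not used here. RMA usually includes quantile normalization of the probe values, which are summarized per feature afterwards. The summarized values of a run need not share 1 distribution. The 5 deposited columns did not, and this does not tell whether they were normalized together. Values were used as deposited, with no filter on low values.

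Features were named through the platform annotation table, with symbols updated by gene identifier. Of 41345 features, 25335 were listed there, 23521 with 1 gene and 1814 with several, and 16010 had no gene listed and are unnamed here. Of the features with 1 gene, 23328 matched the reference gene table of assembly GRCm38 by identifier. No gene was named from a feature with several genes. Where several features named a gene, as for 1082 of 22180 genes, the feature with the highest mean over all 5 arrays was used, and for 6 genes features were called in opposite directions. In 2061 features, and in 1435 genes so represented, the value was the same to the last deposited digit in all 3 DMSO arrays. Control features carry no mark in the identifiers and could not be left out.

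ATRA was compared with DMSO by limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on 2 group means, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 3 residual degrees of freedom and a prior worth 1.52. Every adjusted p of a gene comes from this test. A fold change is on the scale of the deposited log2 values, which compress the change of dim features. Directions and group comparisons of whole lists were tested with camera of the same package, with a preset correlation between genes of 0.01, adjusted over the 43 lists. Every adjusted p of a list comes from camera unless another test is named, and "with an estimated correlation" marks camera with the correlation estimated per list. Counts adjusted over the list alone apply Benjamini-Hochberg within a list. Level-matched random lists were drawn 10000 times in 100 classes of DMSO mean, and a percentile gives the place of a list's median among them.

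The gene lists, the test, the alternatives and the genes to name were fixed before the data were examined. The lists cover retinoid biology, stem and progenitor genes, the cell cycle, growth, metabolism, stress, signalling and markers of other marrow cells, and were written from textbook knowledge. Some were given as patterns on the gene symbol, which also take in relatives such as Rpl7l1 among ribosomal proteins and the kinase gene Eif2ak1 among translation factors. Named genes are, first, up to 12 largest rises and 12 largest falls among genes past the threshold whose ATRA values both lie above or below all DMSO values and whose higher group mean exceeds the median of all features (6.07), leaving out clone and predicted gene names. Second, they are drawn from the 4 members with the smallest p in each list, past the threshold or not. Which of these members the text gives as examples was chosen after their values were seen, in part by whether the direction held with the level trend removed, so the examples look steadier than the 200 genes of the rule, which were all refitted. Last, a fixed set is named whatever its values, made of Rarb, Cyp26a1, Cyp26b1, Dhrs3, Rara, Rarg, Stra6, Myc, Cdkn1c, Cdkn1a, Mki67, Ccnd1, Cdk6, Hlf, Mecom, Procr, Gata2, Itgam, Actb and Gapdh. Cd38 was also in that set and was not analysed here.

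Other settings, fixed beforehand, left out each array in turn, added the replicate number as a block, left out dim features, repeated quantile normalization, centred each array on its median, changed the variance model (intensity trend with robust prior, array weights, no empirical Bayes prior), changed the threshold (adjusted p under 0.1, or at least a 1.5-fold change), averaged the features of a gene, and replaced camera's preset correlation by an estimated one or camera's values by ranks. The test fry was run too, which asks whether a list differs from no change, where camera asks whether it differs from the other genes. Chosen after seeing the data were cyclic loess normalization, removal of the level trend (a loess curve with a span of 0.3 of each ATRA array's difference from the DMSO mean on the DMSO mean, subtracted before the fit), the level-matched lists and the counts of list members by setting.

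The gene and list tests were tested on simulated data for the 22180 genes with the real design. Of 68 genes changed by a log2 size of 1, 0% were called, of 66 changed by 2, 68.2%, and of 66 changed by 4, 98.5%, with 3 false calls among 21920 unchanged genes. A shifted list had a camera p of 2.137e-44 and an unshifted list 0.9313. The simulated noise was independent between genes, equal in spread in both groups and free of a level trend. The real arrays differ in each of these, so the rates of missed and false calls need not hold for them.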

Results

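Hematopoietic stem cells (HSCs) are the rare bone marrow cells from which the blood lineages are renewed. All-trans retinoic acid (ATRA) is the active derivative of vitamin A and the ligand of the retinoic acid receptors. In a study of retinoic acid and stem cell dormancy, a state of deep quiescence, stem and progenitor cells of C57BL/6 mice were kept for 24 h with 5 µM ATRA or with its solvent, DMSO, and HSCs were then sorted by flow cytometry. RNA of the sorted cells was measured on 5 Affymetrix mouse gene-level arrays, 3 for DMSO and 2 for ATRA. The deposited log2 expression values covered 41345 array features, from which 22180 genes were analysed. The number of arrays limits the precision of every value. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

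The ATRA arrays spanned a narrower range of values than the DMSO arrays. The SD over all features was between 1.96 and 1.97 in the DMSO arrays, 1.77 in ATRA replicate 1 and 1.49 in ATRA replicate 2. Across features, which are not independent replicates, Pearson's r was between 0.966 and 0.978 among DMSO arrays and 0.730 between the ATRA arrays. Replicate 1 of ATRA correlated with the DMSO arrays at 0.811 to 0.834, and replicate 2 at 0.602 to 0.641. Genes that were abundant in DMSO had lower values in both ATRA arrays. For the 1223 genes with a DMSO mean from 9 to 10, the median difference from DMSO was -1.36 in ATRA replicate 1 and -2.55 in replicate 2. For the 2790 genes from 4 to 5 it was 0.30 and 0.76. The gene groups described here were therefore also set against 10000 random lists of the same size with the same distribution of DMSO means.

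**Figure D1:**
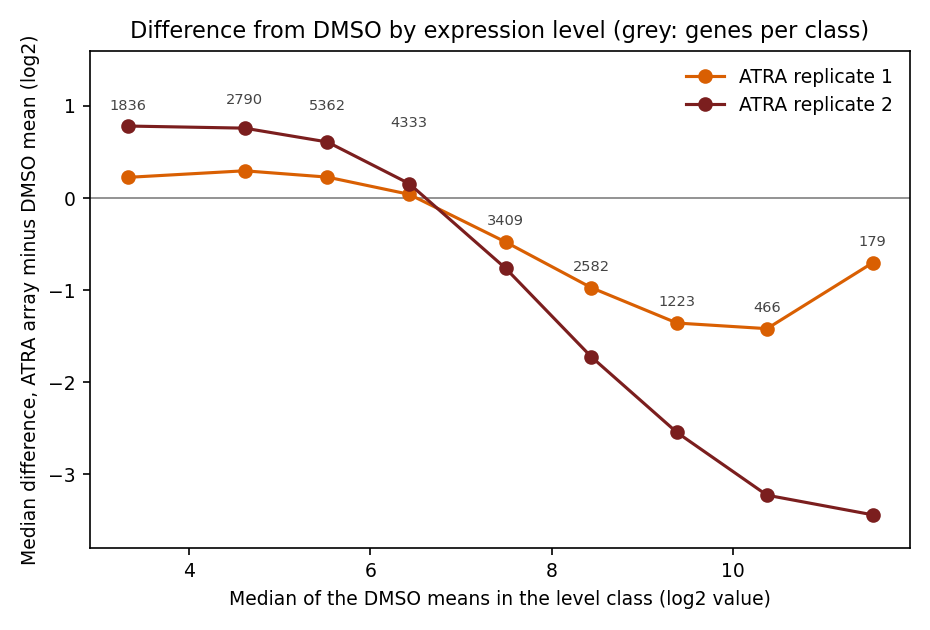
Median log2 difference of each ATRA array from the DMSO mean (vertical axis) in classes of genes by DMSO mean (horizontal axis, median of the class, log2 value), with the number of genes in grey. Between 9 and 10 the difference was -1.36 in replicate 1 and -2.55 in replicate 2, and below 4 it was 0.22 and 0.78.

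The comparison of ATRA with DMSO asked which transcripts of cultured HSCs differ with retinoic acid. Among the 12 largest falls were H2ax, the histone variant phosphorylated at DNA breaks, Tubb5, a beta-tubulin, Shmt2, the mitochondrial serine hydroxymethyltransferase, and Fasn, the fatty acid synthase. H2ax fell by 5.08 on the log2 scale (SE 0.56, adjusted p = 0.0106), from 12.01 ± 0.12 (SD, n = 3) to 7.82 and 6.03 in the ATRA arrays, which is 33.9-fold lower. Fasn was 18.8-fold lower (adjusted p = 0.00697) and Shmt2 19.6-fold lower (adjusted p = 0.00627). With the trend on expression level removed, the log2 changes shrank to -2.02 for H2ax (adjusted p = 0.0616), -1.50 for Fasn (adjusted p = 0.139) and -1.56 for Shmt2 (adjusted p = 0.296), and these calls ended, as did those of Tubb5, Eif3b, Aph1a and Ubl7. The other large falls were those of the histone gene H2ac15, the translation factor Eif3b, the RNA helicase Ddx6, Aph1a, Ubl7, Cyb5b, the mucin Muc13 and the microRNA gene Mir1949, with log2 changes from -5.11 for Mir1949 to -4.07 for Cyb5b. The 12 largest rises were of another kind. They held the vomeronasal receptor genes Vmn1r129, Vmn1r103 and Vmn1r168, the olfactory receptor genes Olfr829 and Olfr935, the microRNA genes Mir680-1 and Mir344d-3, and Pla2g10os, Zfp972, Smok4a, Mterf1b and Sly. Vmn1r129 rose by 5.56 (SE 0.44, adjusted p = 0.0073), from 3.77 ± 0.69 to 9.42 and 9.23, and Sly, the smallest of these rises, by 4.15. With the level trend removed, Olfr829 (4.97 to 4.45, adjusted p = 0.0829) and Olfr935 (4.72 to 4.34, adjusted p = 0.0621) lost their calls, though their rises shrank little. The other 10 kept their calls.

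In all, 4865 of 22180 genes passed a limma adjusted p of 0.05, of which 1437 were higher and 3428 lower with ATRA, and 5783 of 41345 features passed, 2181 higher and 3602 lower. Both ATRA values lay on the same side of the 3 DMSO values in 13781 genes (62.1%). Chance gives 20% only where all arrays have equal spread. The ATRA arrays agreed less with each other than the DMSO arrays did, which raises that share. The 62.1% is therefore no measure of an effect of ATRA. The median gene differed by 0.16, and by -0.11 after each array was centred on its own median, which gave 560 genes higher and 4542 lower. With the trend on expression level removed, 348 genes were higher and 209 lower, and 340 genes were called in the same direction in both fits. No gene passed when DMSO replicate 1, 2 or 3 was left out (limma, 5991, 6065 and 5907 genes at an unadjusted p under 0.05, against 8935 with all arrays). Without ATRA replicate 1 or 2, 14207 and 7683 genes passed. Below, counts of higher and lower members of the lists are also given for 4 settings. Their order is always without ATRA replicate 1, without ATRA replicate 2, after cyclic loess normalization, and with the level trend removed. Without ATRA replicate 1 or 2, the lone ATRA array is assumed to vary like the DMSO arrays. Counts and list calls of these fits leave out the spread between the ATRA arrays and do not show that a change is steady. The smallest p that an exact two-sided permutation test can give with 3 against 2 arrays is 0.1.

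Well known targets of retinoic acid had higher mean values in ATRA, but these differences did not pass the threshold. Dhrs3, a retinal reductase induced by retinoic acid, was at 6.26 ± 0.25 (SD, n = 3) in DMSO and at 7.46 and 6.99 in ATRA (log2 fold change 0.96, SE 0.23, adjusted p = 0.0515). Cyp26a1 and Cyp26b1, the enzymes that break down retinoic acid, differed by 0.88 (SE 0.24, adjusted p = 0.0663) and 0.53 (SE 0.17, adjusted p = 0.0902). Rarb, a receptor gene with a retinoic acid response element (feature 17303609), went from 6.24 ± 0.17 to 6.61 and 6.85 (log2 fold change 0.49, SE 0.16, adjusted p = 0.0965). Stra6, the retinol transporter, differed by 0.47 (adjusted p = 0.0692). For each of these 5 genes both ATRA values lay above all 3 DMSO values, and a separation to either side held for 62.1% of all genes. Among genes of the same DMSO level, the changes lay at percentile 95.9 for Dhrs3, 83.3 for Cyp26a1, 77.0 for Cyp26b1, 73.0 for Rarb and 75.7 for Stra6. The receptor genes Rara and Rarg differed by -0.21 (adjusted p = 0.28) and 0.36 (adjusted p = 0.302). Dhrs3 passed after quantile normalization or with dim features left out. With the level trend removed, the differences were 0.69 for Dhrs3, 0.36 for Cyp26a1, 0.24 for Cyp26b1, 0.21 for Rarb and 0.26 for Stra6, and did not pass.

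Of the 32 genes measured for retinoid metabolism and transport, Bco2, a carotenoid-cleaving enzyme, rose by 0.54 (adjusted p = 0.0421), Retsat, the retinol saturase, fell by 1.57 (adjusted p = 0.0288) and 30 did not pass. Adjusted over the list alone, 0 rose and 0 fell, and under the 4 settings the counts were 17 and 7, 3 and 2, 1 and 0, and 0 and 0. The list's median log2 fold change was 0.45 (camera adjusted p = 0.14), at percentile 97.8 of level-matched random lists, whose median was 0.28, and at 41.9 in ATRA replicate 1 and 98.9 in replicate 2 taken alone. Of 38 retinoid receptors and reported retinoic acid targets, 1 rose, 6 fell and 31 did not pass, and adjusted over the list alone the counts were also 1 and 6. Under the 4 settings they were 8 and 12, 3 and 10, 0 and 1, and 0 and 0. Among those that fell were Icam1, an adhesion molecule (-1.80), Dusp6, a MAP kinase phosphatase (-2.70), Pml (-1.74) and the urokinase receptor gene Plaur (-1.19). The falls of Pml and Plaur turned into differences of 0.26 and 0.04 once the level trend was removed, which also ended the calls of Icam1, Dusp6, Bco2 and Retsat. The list's median was 0.03, its mean -0.31 and its test pointed down (adjusted p = 0.335), at percentile 49.8 of matched lists. With fry, which tests against no change, this list passed as lower (fry adjusted p = 0.0188). The 36 measured HoxA to HoxD genes, classical retinoic acid targets in the embryo, held 0 higher and 1 lower gene, with 0 and 0 adjusted over the list alone (median 0.30, adjusted p = 0.14). Level-matched lists had a median of 0.36, which put the Hox genes at percentile 21.3, and at 7.36 and 67.6 in ATRA replicates 1 and 2 alone. Hox counts under the 4 settings were 17 and 3, 2 and 5, 0 and 1, and 0 and 0, and without ATRA replicate 1 the list passed as higher (adjusted p = 0.00926). Without any 1 of the DMSO arrays, the calls of Bco2, Retsat, Icam1, Dusp6, Pml and Plaur were lost, as for all genes, but their directions stayed.

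**Figure D2:**
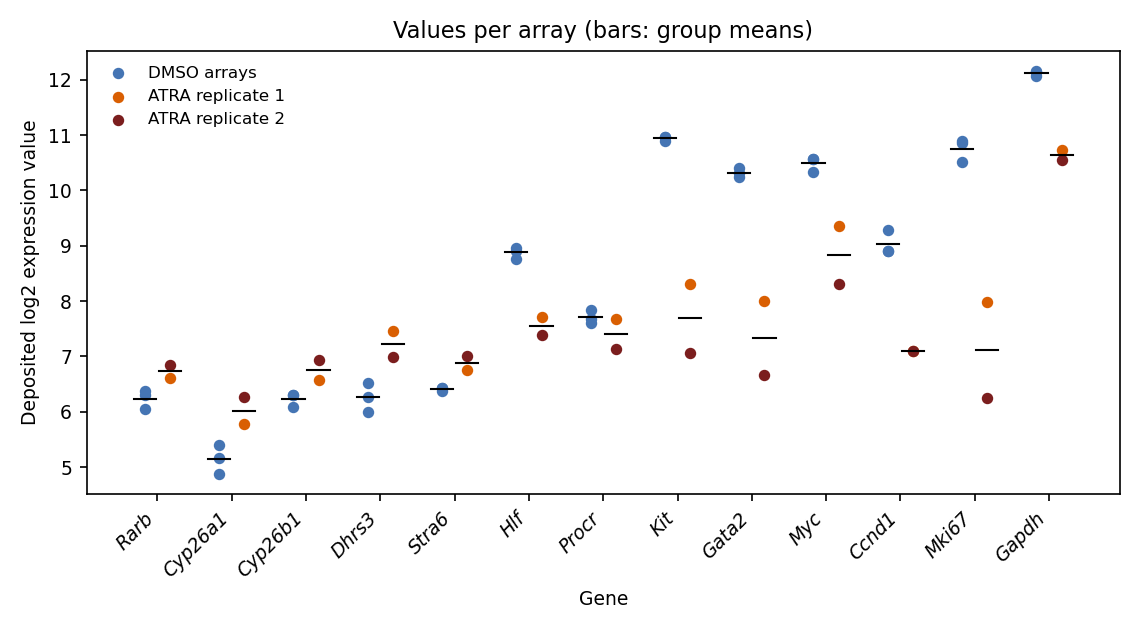
Deposited log2 expression value (vertical axis) of 13 genes fixed or named by rule (horizontal axis) in each array, with blue points for the 3 DMSO arrays, orange and dark red points for ATRA replicates 1 and 2, and bars for group means. Both ATRA values lay above the DMSO values for Rarb, Cyp26a1, Cyp26b1, Dhrs3 and Stra6 and below them for Kit, Gata2, Ccnd1 and Mki67, and the lower values of Myc and Gapdh turned into higher ones after cyclic loess normalization or removal of the level trend.

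The list of HSC genes passed as lower with ATRA under the preset correlation but not with an estimated one, and most of its members did not pass. Of 56 measured HSC genes, 0 rose, 21 fell and 35 did not pass, and adjusted over the list alone 0 rose and 27 fell. HSC gene counts under the 4 settings were 4 and 33, 3 and 24, 3 and 13, and 2 and 1. Kit, the receptor for stem cell factor, fell by 3.25 (SE 0.40, adjusted p = 0.0125), from 10.94 ± 0.04 (SD, n = 3) to 8.32 and 7.06. The transcription factor genes Erg (-2.83), Gata2 (-2.99) and Mecom (-2.17) fell too, as did the lymphotoxin gene Ltb (-2.85). None of these 5 calls was kept with the level trend removed, where Kit differed by -0.65 (adjusted p = 0.281), Erg by -1.22 (adjusted p = 0.108), Gata2 by -0.69 (adjusted p = 0.134), Mecom by -0.72 (adjusted p = 0.148) and Ltb by -0.58 (adjusted p = 0.588). Hlf, a transcription factor gene of primitive HSCs, fell by 1.33 (adjusted p = 0.0115), a change that became 0.20 when the level trend was removed. Procr, the HSC surface marker EPCR, differed by -0.30 (adjusted p = 0.291). The median of the list was -1.03 (camera adjusted p = 9.67e-06, and adjusted p = 0.447 with an estimated correlation). Random lists of the same level had a median of -0.80, which put the HSC genes at percentile 6.88, and at 2.21 and 58.6 in ATRA replicates 1 and 2 alone. The call of the list was lost when dim features were left out (adjusted p = 0.0728), after cyclic loess normalization (adjusted p = 0.0921) and when the level trend was removed.

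Of 21 multipotent progenitor genes, 2 rose, 3 fell and 16 did not pass (2 and 3 adjusted over the list alone, median 0.04, mean -0.02, adjusted p = 0.934, with the test pointing up). Cytokine receptors and their signalling genes fell as a list of 34, with 1 member higher, 12 lower and 21 not past the threshold, or 2 and 15 adjusted over the list alone (median -1.15, adjusted p = 2.05e-05, adjusted p = 0.447 with an estimated correlation). Csf3r, the G-CSF receptor, fell by 2.39 (adjusted p = 0.00747). Of 32 chromatin regulators of stem cells, 0 rose, 11 fell and 21 did not pass, with 0 and 15 adjusted over the list alone. Their median was -1.22 (adjusted p = 5.10e-07, adjusted p = 0.473 with an estimated correlation), against -1.34 in level-matched lists. The DNA methyltransferase Dnmt3b (-2.07) and the methylcytosine dioxygenase Tet3 (-2.05) fell. Both list calls were lost with the level trend removed, as were those of Csf3r, Dnmt3b and Tet3, and the chromatin call also after cyclic loess normalization (adjusted p = 0.37). Under the 4 settings the counts were 4 and 5, 7 and 3, 3 and 2, and 2 and 0 for progenitor genes. They were 3 and 20, 2 and 17, 0 and 6, and 0 and 0 for cytokine receptors, and 1 and 29, 2 and 20, 1 and 3, and 0 and 0 for chromatin regulators.

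The S phase, G2 and M phase and G1 lists had negative median changes in both ATRA arrays. Mki67, the proliferation marker Ki-67, fell by 3.64 (SE 0.55, adjusted p = 0.0192), from 10.76 ± 0.21 (SD, n = 3) to 7.99 and 6.24, which is 12.5-fold lower. With the level trend removed the change was -1.12 and did not pass (adjusted p = 0.0608). Of 62 S phase genes, 0 rose, 32 fell and 30 did not pass, and 0 and 46 did so adjusted over the list alone. Prim1, a DNA primase subunit, was 9.69-fold lower (adjusted p = 0.00627), and the replication licensing factor Cdt1 fell by 2.66. Of 67 G2 and M phase genes, 0 rose, 37 fell and 30 did not pass, with 0 and 45 adjusted over the list alone. The condensin subunit Ncapd2 (-3.14) and the spindle checkpoint kinase Bub1b (-2.06) fell. Of the 15 cyclins and kinases of G1 entry, 0 rose, 7 fell and 8 did not pass, with 0 and 10 adjusted over the list alone. Cyclin D1 (Ccnd1) fell by 1.93 (adjusted p = 0.00771). Cdk6 fell by 3.90 (adjusted p = 0.047), from a mean of 10.48 in DMSO to 8.06 and 5.11 in ATRA replicates 1 and 2, which differ widely. Cdk2 fell by 1.75, a change that became 0.10 with the level trend removed. Of the genes named here, only Prim1 kept its call in that fit (-1.85, adjusted p = 0.0415).

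The medians were -1.91 for S phase and -1.52 for G2 and M phase genes (camera adjusted p = 1.48e-15 each, and adjusted p = 0.447 with an estimated correlation). Level-matched random lists had medians of -1.55 and -1.25, which put the lists at percentiles 0.21 and 1. In the single arrays, S phase genes lay at percentile 14.45 in replicate 1 and 0.04 in replicate 2, and G2 and M phase genes at 0.53 and 2.91. Both lists stayed past the threshold with the level trend removed under the preset correlation (adjusted p = 9.33e-05 and 0.00105), and an estimated one was not run there. Their medians shrank to -0.56 and -0.40, with 2 S phase genes higher and 3 lower and 0 G2 and M phase genes higher and 5 lower. The G1 list had a median of -1.75 (adjusted p = 8.28e-05, adjusted p = 0.447 with an estimated correlation) and lost its call after cyclic loess normalization (adjusted p = 0.0938) and with the trend removed. S phase counts under the 4 settings were 0 and 61, 3 and 42, 1 and 22, and 2 and 3. Those of G2 and M phase genes were 0 and 63, 1 and 41, 2 and 19, and 0 and 5, and those of the G1 list 0 and 13, 0 and 9, 1 and 3, and 0 and 1. Without any 1 DMSO array these calls of members were lost. The medians changed little without DMSO replicate 1, to -1.98 for S phase, -1.56 for G2 and M phase and -1.78 for G1 genes.

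Genes that restrain the cell cycle did not rise as a group. Of 35 inhibitors and quiescence genes, 0 rose, 10 fell and 25 did not pass, with 0 and 12 adjusted over the list alone. Cdkn1a (p21) fell by 2.47 (adjusted p = 0.0253), as did the kinase gene Stk11 (-1.97), the mTORC1 inhibitor Tsc2 (-2.02) and the pocket protein Rbl2 (-1.17), and the change of Rbl2 became 0.08 with the level trend removed, which ended the other 3 calls. Cdkn1c (p57), the inhibitor most tied to quiescent HSCs, was at 6.74 in DMSO and at 6.62 and 6.74 in ATRA (log2 fold change -0.06, adjusted p = 0.67). The deposited value was the same to the last digit in all 3 DMSO arrays, with an SD of 0, and in ATRA replicate 2, so this gene tells little. The list fell with a median of -0.19 (adjusted p = 0.00852, adjusted p = 0.447 with an estimated correlation), at percentile 37.4 of matched lists. With the level trend removed it did not pass (adjusted p = 0.0818), with a median of -0.21. The call of the list was lost without ATRA replicate 1 (adjusted p = 0.181) and with dim features left out (adjusted p = 0.359), and the counts under the 4 settings were 6 and 11, 1 and 15, 0 and 4, and 0 and 0. Of 32 core and linker histones, 0 rose, 5 fell and 27 did not pass, with 0 and 4 adjusted over the list alone (median -0.20, adjusted p = 0.265). Matched lists had a median of 0.11, which put the histones at percentile 0.76, and at 24.8 and 4.43 in ATRA replicates 1 and 2 alone. Histone counts under the 4 settings were 8 and 15, 0 and 9, 0 and 5, and 0 and 1.

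The lists of Myc targets, ribosome biogenesis factors, aminoacyl-tRNA synthetases and translation factors shifted down, and the counts of cytosolic ribosomal proteins depended on the setting. Myc was at 10.49 ± 0.13 (SD, n = 3) in DMSO and at 9.36 and 8.31 in ATRA (log2 fold change -1.66, SE 0.35, adjusted p = 0.0372), a fall that turned into a difference of 0.20 after cyclic loess normalization and of 0.74 with the level trend removed. Of 52 genes in the list of Myc and its targets, 0 rose, 29 fell and 23 did not pass, with 0 and 39 adjusted over the list alone. Cad, which starts pyrimidine synthesis, fell by 3.43 and the nucleolar protein Nop2 fell by 3.35. Of 60 ribosome biogenesis factors, 0 rose, 36 fell and 24 did not pass, with 0 and 45 adjusted over the list alone, among them the helicase Ddx21 (-4.04) and the RNA polymerase I subunit Polr1b (-3.05). Of 18 aminoacyl-tRNA synthetases, 0 rose, 14 fell and 4 did not pass, with 0 and 18 adjusted over the list alone, and Iars (-3.30) and Wars (-3.19) fell. Of 63 translation initiation and elongation factors, 1 rose, 23 fell and 39 did not pass, with 2 and 30 adjusted over the list alone.

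The median was -2.50 for the synthetases (adjusted p = 6.03e-09), -1.66 for ribosome biogenesis (adjusted p = 8.40e-15), -1.66 for Myc targets (adjusted p = 5.36e-14) and -1.49 for translation factors (adjusted p = 2.96e-08). With an estimated correlation, adjusted p = 0.447 for the first 3 lists and 0.473 for translation factors. Against level-matched lists these medians lay at percentile 0.11 for the synthetases, 2.14 for ribosome biogenesis, 29.1 for Myc targets and 14.4 for translation factors. In ATRA replicates 1 and 2 alone they lay at 0.12 and 3.75, 20.9 and 3.73, 2.08 and 47.2, and 20.3 and 8.41. These 4 list calls were lost with the level trend removed, and of the genes named for them only Ddx21 kept its call (-1.96, adjusted p = 0.0494). Myc target counts under the 4 settings were 0 and 44, 1 and 37, 2 and 10, and 1 and 0, and ribosome biogenesis counts 1 and 54, 1 and 38, 2 and 15, and 3 and 5. Those of the synthetases were 0 and 17, 0 and 16, 0 and 7, and 0 and 1, and those of translation factors 5 and 53, 6 and 37, 5 and 10, and 3 and 1.

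Of 67 cytosolic ribosomal proteins, 7 rose, 3 fell and 57 did not pass, with 6 and 3 adjusted over the list alone. Rps26 rose 2.95-fold (adjusted p = 0.0073) and Rpl17 2.83-fold (adjusted p = 0.0112). Rpl7l1 (-2.69), a relative taken in by its symbol, and Rplp0 (-1.45) fell, the last a call that ended with the level trend removed. The counts were 11 higher and 41 lower without ATRA replicate 1, 27 and 14 without replicate 2, 12 and 2 after cyclic loess normalization, and 15 and 1 with the level trend removed. The list's median was -0.25 (adjusted p = 0.335), above 100% of level-matched lists, whose median was -1.13. Lists matched on gene span as well had a median of -0.58, which put these genes at percentile 93.8, and at 99.6 and 55.2 in ATRA replicates 1 and 2 alone. Its direction depended on the array and the scaling, with a median of 0.22 in ATRA replicate 1 and -0.99 in replicate 2, a fall without replicate 1 (adjusted p = 2.03e-05) and a rise after cyclic loess normalization (adjusted p = 9.52e-05). Of 71 mitochondrial ribosomal proteins, 0 rose, 15 fell and 56 did not pass (0 and 15 adjusted over the list alone), among them Mrpl37 (-1.94), whose call ended with the level trend removed. Their counts under the 4 settings were 1 and 61, 18 and 25, 7 and 5, and 5 and 0. Their median was -0.70 (adjusted p = 5.69e-06, adjusted p = 0.529 with an estimated correlation), against -1.15 in level-matched lists and -0.94 in lists matched on span as well. In the latter they lay at percentile 98.4, and at 99.9 and 13.3 in ATRA replicates 1 and 2 alone. The fall turned into a rise that did not pass after cyclic loess normalization (adjusted p = 0.235) or with the level trend removed (adjusted p = 0.0797). The call was also lost without ATRA replicate 2 (adjusted p = 0.469).

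The lists of glycolysis, cholesterol biosynthesis, the tricarboxylic acid cycle and fatty acid oxidation shifted down, while the direction of the respiratory chain subunits depended on the setting. Of 22 glycolysis genes, 0 rose, 12 fell and 10 did not pass, with 0 and 12 adjusted over the list alone. Triosephosphate isomerase (Tpi1) fell by 3.71 (SE 0.12, adjusted p = 0.00627). Gapdh, often used as a reference gene, fell by 1.48 (adjusted p = 0.00739), which became 0.84 after cyclic loess normalization and 1.63 with the level trend removed. Genes with a DMSO mean of 11 or more, Gapdh among them, had a median change of -2.22, and Gapdh lay at percentile 65.8 of its level. Its move from -1.48 to 1.63 exceeded that median, so the size of the turned value is uncertain. Another reference gene, Actb, fell by 2.30 (adjusted p = 0.00892). Of 19 cholesterol biosynthesis genes, 0 rose, 13 fell and 6 did not pass, with 0 and 17 adjusted over the list alone. Squalene epoxidase (Sqle) fell by 3.15 and the sterol regulator Srebf2 fell by 3.11. Of 23 tricarboxylic acid cycle genes, 0 rose, 10 fell and 13 did not pass, with 0 and 15 adjusted over the list alone, and citrate synthase (Cs) fell by 2.45 and Idh3a fell by 3.32. Of 21 fatty acid oxidation genes, 0 rose, 10 fell and 11 did not pass, with 0 and 15 adjusted over the list alone, Hadh among them (-2.12).

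The medians of these 4 lists were -1.10 (adjusted p = 5.49e-07), -1.78 (adjusted p = 6.03e-09), -1.42 (adjusted p = 3.26e-07) and -1.12 (adjusted p = 2.05e-05), and adjusted p = 0.447 with an estimated correlation for each. They lay at percentiles 7.61, 11.9, 61.6 and 66.1 of level-matched lists, with 0.68 and 32.8 for glycolysis and 1.24 and 64 for cholesterol in ATRA replicates 1 and 2 alone, and all 4 calls were lost with the level trend removed. Of the genes named for these lists, only Idh3a kept its call then (-1.66, adjusted p = 0.0256), as did Actb (-1.60, adjusted p = 0.0371). After cyclic loess normalization the calls of cholesterol biosynthesis (adjusted p = 0.0706), the tricarboxylic acid cycle (adjusted p = 0.19) and fatty acid oxidation (adjusted p = 0.28) were lost. Glycolysis counts under the 4 settings were 0 and 14, 0 and 12, 0 and 5, and 0 and 1, and cholesterol counts 0 and 19, 0 and 16, 0 and 4, and 0 and 0. Those of the tricarboxylic acid cycle were 0 and 21, 0 and 17, 1 and 5, and 1 and 1, and those of fatty acid oxidation 0 and 15, 1 and 9, 0 and 2, and 0 and 0. Of 25 antioxidant genes, 0 rose, 4 fell and 21 did not pass, with 0 and 4 adjusted over the list alone (median -0.66, adjusted p = 0.0553). This list passed as lower without ATRA replicate 1 (adjusted p = 0.00209), without DMSO replicate 1 (adjusted p = 0.0419) and with array weights (adjusted p = 0.0392), and its counts under the 4 settings were 2 and 14, 4 and 5, 1 and 0, and 1 and 0. Of 79 respiratory chain and ATP synthase subunits, 4 rose, 9 fell and 66 did not pass, with 4 and 8 adjusted over the list alone. The counts were 10 higher and 51 lower without ATRA replicate 1, 33 and 12 without replicate 2, 25 and 7 after cyclic loess normalization, and 20 and 1 with the level trend removed. The ATP synthase subunit Atp5k rose by 1.24 (adjusted p = 0.0179), and Sdha (-3.17) and Uqcrc1 (-2.32) fell, the latter a change that became 0.22 with the level trend removed, which also ended the call of Sdha. The median was -0.25 (adjusted p = 0.226), against -1.46 in level-matched lists and -1.22 in lists matched on span as well. This put the median at percentile 100 under either matching, in both ATRA arrays together and in each alone. It was 0.19 in ATRA replicate 1 and -1.04 in replicate 2, and the list passed as lower without replicate 1 (adjusted p = 3.79e-07) and as higher without replicate 2 (adjusted p = 0.00362) or after cyclic loess normalization (adjusted p = 1.09e-07).

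Stress and signalling lists were lower or did not pass the test. Of 46 autophagy and lysosome genes, 0 rose, 23 fell and 23 did not pass, with 0 and 26 adjusted over the list alone, and the lysosomal genes Hexa (-2.57) and Npc1 (-1.44) fell (list median -1.15, adjusted p = 4.43e-09, adjusted p = 0.447 with an estimated correlation). Of 30 unfolded protein response genes, 0 rose, 16 fell and 14 did not pass, with 1 and 18 adjusted over the list alone, and the chaperone gene Calr (-2.60) and the ubiquitin ligase gene Syvn1 (-1.78) fell (median -1.41, adjusted p = 2.49e-06, adjusted p = 0.447 with an estimated correlation). Of 20 heat shock proteins, 0 rose, 6 fell and 14 did not pass, with 0 and 6 adjusted over the list alone, Hsph1 (-2.87) and Dnajb1 (-1.55) among them (median -1.63, adjusted p = 0.000279, adjusted p = 0.459 with an estimated correlation). Of 48 interferon response genes, 1 rose, 11 fell and 36 did not pass, with 1 and 11 adjusted over the list alone. Gbp6, a guanylate-binding protein, rose by 1.18, and Lgals3bp fell by 3.14 (median -0.90, adjusted p = 2.05e-05, adjusted p = 0.529 with an estimated correlation). Of 32 p53 targets and apoptosis genes, 1 rose, 7 fell and 24 did not pass, with 1 and 8 adjusted over the list alone. The death receptor gene Tnfrsf10b (-1.78) and the survival gene Bcl2 (-2.01) fell (median -0.57, adjusted p = 0.00936, adjusted p = 0.447 with an estimated correlation).

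The medians of these 5 lists lay at percentiles 43.1, 40.8, 8.31, 28.8 and 2.91 of level-matched lists, and the 5 list calls were lost with the level trend removed, as were those of the interferon (adjusted p = 0.0634) and p53 lists (adjusted p = 0.202) with dim features left out. Cyclic loess normalization ended the calls of the lysosome (adjusted p = 0.235), unfolded protein (adjusted p = 0.292) and interferon lists (adjusted p = 0.485). Lysosome counts under the 4 settings were 0 and 37, 5 and 28, 2 and 7, and 3 and 3, and unfolded protein counts 2 and 24, 2 and 21, 0 and 4, and 0 and 0. Those of heat shock proteins were 0 and 16, 2 and 12, 1 and 4, and 0 and 1, those of the interferon response 5 and 20, 2 and 11, 0 and 3, and 1 and 1, and those of p53 targets 2 and 16, 2 and 10, 0 and 4, and 0 and 0. Of 28 immediate early genes, 0 rose, 6 fell and 22 did not pass, with 0 and 9 adjusted over the list alone (median -0.35, adjusted p = 0.0627), and the list passed as lower after median centring (adjusted p = 0.0158) and without DMSO replicate 1 (adjusted p = 0.0494) or 3 (adjusted p = 0.035). Of 35 inflammatory and NF-kappaB genes, 1 rose, 4 fell and 30 did not pass, with 1 and 4 adjusted over the list alone (median -0.09, adjusted p = 0.417). Of 68 integrins and adhesion receptors, 7 rose, 9 fell and 52 did not pass, with 7 and 9 adjusted over the list alone (median 0.24, mean -0.08, adjusted p = 0.534, with the test pointing up). Under the 4 settings immediate early genes counted 6 and 8, 1 and 7, 0 and 0, and 0 and 0, inflammatory genes 5 and 6, 6 and 2, 1 and 1, and 1 and 0, and integrins 26 and 17, 7 and 10, 3 and 3, and 0 and 0. Calls of single members in these lists were lost without any 1 DMSO array, and with the level trend removed only Npc1 of the genes named here kept its call (-1.07, adjusted p = 0.0402).

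**Figure D3:**
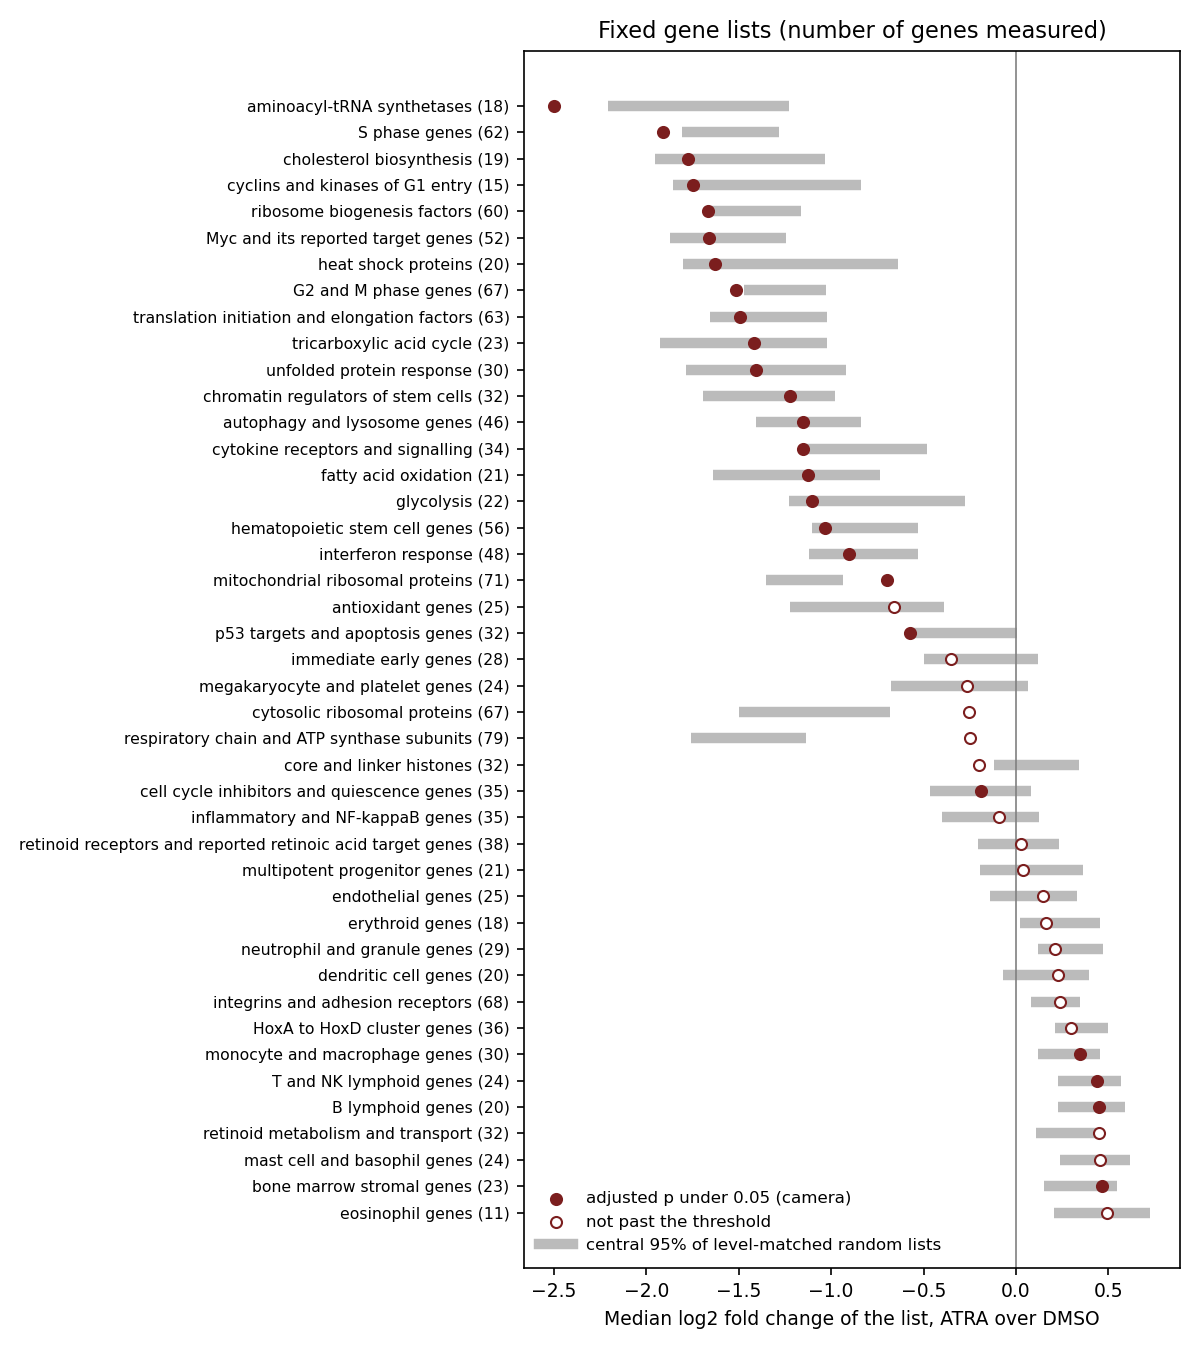
Median log2 fold change of ATRA over DMSO (horizontal axis) for each of the 43 gene lists (vertical axis, genes measured in brackets), filled where the camera adjusted p was under 0.05, with grey bars for the central 95% of level-matched random lists. The synthetases (-2.50), S phase genes (-1.91), G2 and M phase genes, ribosome biogenesis factors and histones lay below their bars. Retinoid metabolism and transport lay just above its bar (0.4515 against 0.4479), though not in ATRA replicate 1 alone. The ribosomal protein lists and the respiratory chain subunits, whose direction changed after cyclic loess normalization, also lay above theirs. With gene span matched as well, the cytosolic ribosomal proteins lay within the range.

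Marker genes of other blood and marrow cells, which the sort could have let through, were mostly dim, and 4 of these lists rose. Of 20 B lymphoid genes, 2 rose (Ighm by 1.26 and Blnk by 0.82), 0 fell and 18 did not pass, and 1 rose adjusted over the list alone (median 0.45, adjusted p = 0.00282, adjusted p = 0.459 with an estimated correlation). Of 24 T and NK lymphoid genes, 4 rose (Klrd1 by 1.35, Cd8b1 by 0.93, Cd3g by 0.57 and Lef1 by 0.54), 0 fell and 20 did not pass, and 0 rose adjusted over the list alone (median 0.44, adjusted p = 0.00535, adjusted p = 0.499 with an estimated correlation). Of 30 monocyte and macrophage genes, 4 rose (Cx3cr1 by 1.04, Cd163 by 0.89, Lyz1 by 0.79 and Fcgr3 by 0.76), 0 fell and 26 did not pass, and 4 rose adjusted over the list alone (median 0.35, adjusted p = 0.0181, adjusted p = 0.447 with an estimated correlation). Of 23 bone marrow stromal genes, 1 rose (Dcn, the proteoglycan decorin, by 0.90), 0 fell and 22 did not pass, and 0 rose adjusted over the list alone (median 0.47, adjusted p = 0.025, adjusted p = 0.593 with an estimated correlation). The DMSO medians of these 4 lists were 5.59, 5.76, 5.90 and 5.84, and their shifts lay at percentiles 68.4, 69.8, 75.6 and 89.1 of level-matched lists, with 100 and 25.5 for monocyte and macrophage genes in ATRA replicates 1 and 2 alone. Removing the level trend ended all 4 list calls and those of the named members except Ighm and Cx3cr1, leaving out ATRA replicate 1 that of monocytes (adjusted p = 0.429) and leaving out replicate 2 that of stroma (adjusted p = 0.132). Cyclic loess normalization also ended the 4 calls (adjusted p = 0.29, 0.235, 0.182 and 0.309), and quantile normalization those of B lymphoid (adjusted p = 0.0586) and stromal genes (adjusted p = 0.101). B lymphoid counts under the 4 settings were 12 and 0, 5 and 1, 1 and 0, and 1 and 0, and T and NK counts 18 and 3, 9 and 0, 2 and 0, and 0 and 0. Those of monocytes were 11 and 5, 9 and 0, 2 and 0, and 2 and 0, and those of stroma 17 and 1, 1 and 0, 1 and 0, and 0 and 0.

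The other 7 marker lists did not pass. Of 24 megakaryocyte and platelet genes, 0 rose and 6 fell, or 1 and 6 adjusted over the list alone, with Itga2b (CD41) down 4.19-fold (median -0.27, adjusted p = 0.113). Of 24 mast cell and basophil genes, 1 rose and 2 fell, or 0 and 2 adjusted over the list alone, the protease Mcpt1 by 1.56 and, downward, Kit and Gata2, which HSCs also express (median 0.45, adjusted p = 0.0809). Without ATRA replicate 2 this list passed as higher (adjusted p = 0.00644). Of 29 neutrophil and granule genes, 1 rose and 2 fell, and likewise over the list alone, with S100a9 0.81 higher and Csf3r lower (median 0.21, adjusted p = 0.306), and Itgam (CD11b) differed by -0.36 (adjusted p = 0.203). Of 11 eosinophil genes, 1 rose and 0 fell, or 0 and 0 adjusted over the list alone (median 0.49, adjusted p = 0.0605), and the list passed as higher without ATRA replicate 1 (adjusted p = 0.0287) and with array weights (adjusted p = 0.034). Of 20 dendritic cell genes, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (median 0.23, mean -0.04, adjusted p = 0.588). Of 25 endothelial genes, 1 rose and 4 fell, or 3 and 6 adjusted over the list alone (median 0.15, mean -0.10, adjusted p = 0.809). Of 18 erythroid genes, 0 rose and 2 fell, or 0 and 0 adjusted over the list alone (median 0.16, mean -0.09, adjusted p = 0.891). For the dendritic, endothelial and erythroid lists the test pointed up, against the sign of the mean. Megakaryocyte counts under the 4 settings were 3 and 9, 3 and 9, 1 and 1, and 1 and 0, mast cell counts 9 and 4, 10 and 2, 1 and 2, and 0 and 0, and neutrophil counts 9 and 4, 2 and 2, 1 and 1, and 0 and 0. Eosinophil counts were 8 and 0, 1 and 0, 0 and 0, and 0 and 0, and dendritic cell counts 7 and 4, 5 and 2, 0 and 2, and 0 and 0. Endothelial counts were 8 and 8, 5 and 5, 2 and 1, and 0 and 0, and erythroid counts 5 and 3, 4 and 2, 0 and 0, and 0 and 0. The calls of Itga2b, Mcpt1 and S100a9 ended with the level trend removed.

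Taken over the 43 lists, 25 passed with the preset correlation, 4 higher and 21 lower. With an estimated correlation 0 passed (camera, 1 list at an unadjusted p under 0.05), and the test on ranks gave 28. The rotation test fry, which tests a list against no change rather than against the other genes, gave 27 and is not a version of the same question. After cyclic loess normalization 13 lists passed and with the level trend removed 4. These 4 were the S phase and G2 and M phase lists as lower and the cytosolic ribosomal and respiratory chain lists as higher (adjusted p = 5.14e-10 and 2.03e-12). An estimated correlation was used with the main fit alone. The 13 and the 4 calls therefore rest on the preset correlation of 0.01.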

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

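The test of multicopy loci was set down before its result was seen. In array features that the gene comparison did not use, many values were higher with ATRA. Of 674 features that list 3 or more genes, 208 were higher (30.9%) and 18 lower, and of 16010 features with no gene listed, 1137 were higher (7.1%) and 700 lower. Of the 23521 features that name 1 gene, 775 were higher (3.29%) and 2783 lower. Leaving out any 1 DMSO array ended all of these calls, with 0 features past the threshold (limma, 9546, 9491 and 9150 features at an unadjusted p under 0.05).

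A candidate explanation for the rise of features from multicopy loci is background that scales with the number of genomic copies, from genomic DNA or transcribed repeats, which would raise such features more than single-copy ones of the same level. Among features with a DMSO mean under 6, those listing 3 or more genes (408) exceeded those listing 1 gene (10797) at the same level by a median of 1.396 in ATRA replicate 1 (bootstrap interval 1.206 to 1.618) and 0.4107 in replicate 2 (0.3138 to 0.563). Both values lie above the 0.2 set down for this explanation. The features tested are those that showed the rise, so the test largely repeats the pattern and decides nothing on its cause, and background stays open, although the labels' protocols include a DNase step. A rise of repeat-rich transcripts under ATRA is the biological alternative and was not tested, since these arrays do not separate DNA from RNA.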

How the results depend on the processing

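Cyclic loess normalization and removal of the level trend were chosen only after the results were seen. Genes past the threshold, 4865 with all arrays, ranged from 0 to 14207, features from 0 to 22970 and lists from 25 to 28 when each array was left out. The 0 came with each DMSO array, where 2 arrays are compared with 2; without ATRA replicate 1 or 2 a lone array is assumed to vary like the DMSO arrays, and 14207 and 7683 genes and 22970 and 11049 features passed. Array weights also gave 0 genes and 0 features (limma, 4377 and 7255 at an unadjusted p under 0.05), with a weight of 0.137 on each ATRA array. Quantile normalization gave 2182 genes and 3257 features, no empirical Bayes prior 1691 and 1806, adjusted p under 0.1 7755 and 10776, cyclic loess 2275 and 3157, and removal of the level trend 557 and 1260. Features higher and lower were 1227 and 4785 after median centring, 1595 and 1562 after cyclic loess and 914 and 346 with the trend removed. Leaving out dim features (516 genes higher, 3735 lower), the intensity trend, the 1.5-fold floor and the mean of features stayed within 1.5 times the main count. Lists past the threshold went from 25 to 13 after cyclic loess, to 4 with the trend removed and to 0 with an estimated correlation. Single list calls were also lost with dim features left out (HSC genes, cell cycle inhibitors, mitochondrial ribosomal proteins, interferon response, p53 targets), after quantile normalization (mitochondrial ribosomal proteins, B lymphoid and stromal genes) and with fry (mitochondrial ribosomal proteins, interferon response, stromal genes). With fry, list calls were gained as lower for retinoic acid targets, histones, megakaryocyte and immediate early genes, and as higher for mast cell genes. List calls were also gained on ranks (immediate early, mast cell and eosinophil genes), with the block (antioxidant and immediate early genes) and with the mean of features (eosinophil genes). The cause was not tested.

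As a replicate block, the replicate number gave 0 genes and 0 features (limma, 5412 and 7635 at an unadjusted p under 0.05). Only numbers 1 and 2 are shared by both groups, and the labels do not say that they pair. The deviations of same-numbered arrays correlated at 0.134 and 0.0983 across genes. These values are not independent, since the deviations of the 2 ATRA arrays mirror each other. The block also leaves fewer than the 3 residual degrees of freedom of the main fit, as DMSO replicate 3 takes a block of its own. The block is therefore no evidence on the size of an effect.

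Among results past the threshold before or after, directions turned in these cases, and the cause was not tested beyond the level trend itself. Cytosolic ribosomal proteins rose after cyclic loess (adjusted p = 9.52e-05) and with the trend removed (5.14e-10), as did the respiratory chain (1.09e-07 and 2.03e-12, and from 3.79e-07 to 0.275 when each array was left out, with a rise at 0.00362 without ATRA replicate 2). Mitochondrial ribosomal proteins pointed up at 0.235 and 0.0797. With the trend removed, fatty acid oxidation (adjusted p = 0.978), the interferon response (0.988), the unfolded protein response (0.898) and chromatin regulators (0.967) pointed up without passing. Of lists past the threshold in neither fit, 8 turned with the trend removed (antioxidant, inflammatory and megakaryocyte lists to up, Hox, neutrophil, integrin, endothelial and erythroid lists to down), as did Procr (-0.30 to 0.42), Ear10, Hoxc8 and Ms4a1. Log2 changes became positive with the trend removed for Pml (0.263), Plaur (0.0387), Hlf (0.204), Cdk2 (0.104), Rbl2 (0.0787), Uqcrc1 (0.221), Cat (0.0884), Fdft1 (0.0481), Ifi35 (0.126), Klf6 (0.0688), Ncoa2 (0.208), Sdhb (0.245), Tap1 (0.0391), Ccnc (0.239, and 0.00271 after cyclic loess), Myc (0.737, and 0.202 after cyclic loess) and Gapdh (1.63, and 0.842). Of the 200 genes of the naming rule, 174 passed, and of these 174 lost significance without any 1 DMSO array, under array weights or under the block, 44 after quantile normalization, 87 after cyclic loess and 146 with the trend removed, turned ones included. All 174 kept their direction without any 1 DMSO array, under array weights and under the block. Values restricted to features without _s, _x or _a endings were not run, since the identifiers have no such endings.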

Other observations

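The test of quantile normalization and that of the slopes of the ATRA arrays were chosen only after the results were seen, as were the genes and families of the first paragraphs. The mitochondrial genome encodes core subunits of the respiratory chain. Of 10 of its transcripts measured, 5 rose, 0 fell and 5 did not pass, and in 6 both ATRA values lay above all 3 DMSO values. ND6, the protein-coding gene on the light strand of mitochondrial DNA, rose from 8.38 ± 0.0847 (SD, n = 3) to 11.53 and 11.24 (SE of the log2 change 0.146, adjusted p = 0.00627), and stayed past the threshold with the level trend removed (adjusted p = 0.0126). ND4L rose by 1.73, ND3 by 1.40, ND2 by 1.02 and ND5 by 0.65. COX1, ND4 and CYTB differed by -0.44, -0.48 and -0.75 and did not pass, and these signs turned after cyclic loess normalization or with the level trend removed. Removal of the trend may overshoot for such bright transcripts, as ND1 went from 0.25 to 3.59. Genes with a DMSO mean of 11 or more had a median change of only -2.22. ND4 passed as lower after median centring (adjusted p = 0.0495), and the rise of ND5 passed under none of the other scalings. COX3, which differed by 0.47 (adjusted p = 0.263), passed as higher with the trend removed (adjusted p = 0.0493). The rise of ND2 was lost after cyclic loess (adjusted p = 0.0748) and with the trend removed (adjusted p = 0.0577), whereas ND3, ND4L and ND6 passed under median centring, quantile normalization, cyclic loess and removal of the trend. Leaving out any 1 DMSO array ended these calls, as it did for all genes.

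Receptor genes of the nose held rises and no falls. Of 1088 olfactory receptor genes, 158 rose and 0 fell (median 0.64), of 176 Vmn1r genes 45 rose and 0 fell (median 0.69), and of 109 Vmn2r genes 19 rose and 0 fell (median 0.60). Their DMSO medians were 4.02, 3.74 and 3.45, at the dim end of the arrays, where all genes with a DMSO mean under 4 had a median of 0.57 and those from 4 to 5 a median of 0.56. With the level trend removed their medians were 0.15, 0.21 and 0.11, with 11, 17 and 2 genes higher and 0 lower. The sign of the median of each family was kept under all 4 other scalings. Of 483 microRNA genes, 57 rose and 5 fell, and of 73 small nucleolar RNA genes, 2 rose and 10 fell (median -0.62). With the level trend removed, 14 and 1 microRNA genes and 0 and 2 small nucleolar RNA genes did.

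The narrower range of the ATRA arrays may come from values that were never brought to a common distribution, from RNA quality or amplification that loses long transcripts, or from ATRA itself. After quantile normalization, 42% of the called genes were still called in the same direction. That normalization gives all arrays 1 range by construction, so this value decides nothing on the cause, and the first stays open. Among 1860 genes with a DMSO mean of at least 9, the partial Spearman correlation of fold change with gene span, given level, was -0.2902 in ATRA replicate 1 and -0.3164 in replicate 2 (permutation p = 1e-05 each, the smallest that 1e+05 resamples can give). Both values met the bound set down for loss of long transcripts before the result was seen, so its prediction held. Gene span stands in for transcript length, so this explanation is not settled and stays open. The slopes on the DMSO mean were -0.24262 and -0.51579, against -0.0198 to -0.00937 in the DMSO arrays. Such a spread between 2 single samples decides nothing when set against DMSO arrays that may be technical replicates, and an effect of ATRA cannot be told apart from array quality with 2 arrays.

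The fall of S phase and G2 and M phase genes could be part of the general fall of abundant transcripts or of a loss of long ones, or a slower cell cycle under retinoic acid. The 129 genes together had a median of -1.634, against -1.372 in level-matched lists, at percentile 0.35, and at 0.43 and 0.01 in ATRA replicates 1 and 2 taken alone, against a bound of 0.5. With 2 standard errors of the 10000 draws added, an allowance made after the result was seen, replicate 1 reached 0.56 and missed the bound. Random lists also hold unrelated genes, whereas the estimated correlation was 0.63 among S phase and 0.44 among G2 and M phase genes, and both lists had adjusted p = 0.447 with it, so level as the cause stays open. Neither list alone met the bound in both arrays (14.45 and 0.04 for S phase, 0.53 and 2.91 for G2 and M phase). Matched on gene span as well, they lay at percentile 0.27, and at 0.7 and 0.03 in the single arrays. The first of these missed the bound and span is not transcript length, so loss of long transcripts stays open too. A biological slowing is a hypothesis that these values leave open as well.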
